A study of Homo sapiens with 8 samples.

How the data were processed

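RNA of 8 cultures was measured, 1 culture per array: the human colon cancer lines HCT116 and DLD1, each with its parental culture and 3 oxaliplatin-resistant clones. Per the labels, the cells were grown for 24 h in medium with 10% serum and no drug, RNA was extracted with TRIzol, and 0.1 µg was labelled with Cy3 with the Low Input Quick Amp kit. The deposited scanner files hold spot intensity on a linear scale, as processed by the authors with Agilent Feature Extraction 10.7.3.1 per the submitters' processing notes. Per the file headers the protocol was GE1_107_Sep09 and probe positions are on the human genome hg19 (GRCh37). The deposited series matrix holds an intensity per probe that the files do not describe. Set against the scanner values, each of its columns equalled the processed signal divided by that array's 75th percentile over all features, on a linear scale and without centring of genes. Its medians were 0.062, 0.0759, 0.065 and 0.0566 for the HCT116 parent, OHP1, OHP3 and OHP5, and 0.0692, 0.0668, 0.072 and 0.0696 for the DLD1 parent, OHP1, OHP4 and OHP5. Other deposited columns, the marks for spots well above background, for saturation and for outlying spots, were used as the authors' software set them.

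All arrays lay on 1 slide and were scanned on 1 day, so no block for slide or scan was fitted. HCT116 arrays filled slide row 1 and DLD1 arrays slide row 2, and both parents lay in slide column 1, so line cannot be told apart from slide row, nor parent from column. Each array had 62976 spots, of which 61657 were not controls. The 3360 spots of ERCC spike-in probes were left out, and the spots of each of the 50599 distinct remaining probes were averaged. Through their accessions 28174 probes took a current gene symbol, 2618 kept a symbol that is still current, 620 were matched by a unique synonym, and 19187 kept the name in the file. The reference used for these names follows GRCh38, and none of its positions were used.

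Values are log2 of the processed signal minus the array's 75th percentile over non-control probes. A probe was tested when it was well above background on every array of at least 1 of the 4 groups, spots marked as outliers were left out on their array (12 values among tested genes), and each gene was represented by the probe with the highest mean, which left 21331 genes or transcripts. Probes of a called and named gene were compared where they passed this filter. They pointed in opposite directions for SLC9B1 among the DLD1 clones and for CASP10 and RIGI between the lines.

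Comparisons were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the package data.table at version 1.17.8. Adjusted p means the two-sided Benjamini-Hochberg value over all genes of a comparison, with a threshold of 0.05. The 5 fitted comparisons were resistant clones against parents over both lines with line as a term, clones against parent in each line from 1 fit of 4 groups, the difference between these effects, and HCT116 against DLD1 with resistance as a term. Values with ± are log2 differences with the standard error of the fit, from 3 clones and 1 parent array per line unless stated. Nothing in the labels says whether repeat cultures exist, so p-values measure only the spread between clones, and each parent, with 1 array, is assumed to vary like the clones. The number of arrays limits the precision.

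Where a gene was not well above background on any array of a group, only a lower bound of the fold can be given. It is written "at least", and sets the mean of the brighter group against the mean of, per array, the higher of the gene's own value and the lowest signal among probes well above background. List medians were computed again with such members at their bound and members below background in both groups left out, and are given for some of the lists. Where a gene was above background on some arrays of a group and not on others, that number is given, and its log2 difference rests partly on background.

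The design, the tests and 31 gene lists were fixed before the data were examined, 30 of which are described: platinum and copper transport, ABC efflux pumps, metallothioneins, glutathione and NRF2, nucleotide excision repair, mismatch repair, base excision repair, homologous recombination and Fanconi, translesion synthesis, apoptosis, epithelial adhesion, mesenchymal genes, WNT targets, colonic differentiation, interferon response, antigen presentation, NF-kB and inflammation, cell cycle, nucleotide metabolism, hypoxia and glycolysis, unfolded protein response and ATF4, cholesterol synthesis, cancer-testis antigens, receptor tyrosine kinase signalling, markers of fibroblasts, blood, endothelium and neural cells, ribosomal proteins, and reference genes. They name 845 genes, of which 834 were on the array and 733 were tested. In all, 30 genes stand in more than 1 list. Lists were tested with camera (limma) at a preset correlation of 0.01, with adjustment over the 31 lists of a comparison, and again with a correlation estimated from the data. Members that passed are counted over all genes and adjusted over the list alone. Medians of a list in a single clone are set against 10000 random lists of the same size matched on mean level.

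Named genes followed a fixed rule. In each comparison these were the 12 highest and 12 lowest log2 differences among genes with adjusted p under 0.05 that have a symbol, are not Y-linked and not XIST, and changed the same way in each clone compared. Where under 5 genes of a direction passed, the 5 with the largest moderated statistic are named and said not to pass. For a described list up to 4 members with the largest moderated statistic are given. SLC31A1, ATP7A, ATP7B, ABCB1, ABCC2, GSTP1, ERCC1, XPA, MSH6, CDKN1A, MDM2 and BAX are always named. Some genes that the rule names, and 1 gene list, were measured and tested but are left out of the text and the plots. Genes 2-fold apart from the parent in all 3 clones of a line were counted without a test, beside 100 simulations of unchanged arrays sharing a parent.

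Alternatives were normexp background correction (offset 50), quantile and median scaling, the series matrix values, other filters on dim probes, other probe rules, eBayes with trend and robust, outlying spots kept, other thresholds, other sets of arrays and covariates, the clone number as a block, and leaving out each array in turn. A filter of at least 3 arrays well above background, a common floor at a normalized log2 value of -3.70, and a 75th percentile over probes detected on all 8 arrays were added after seeing the data.

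The fit was tested on simulated data with 200 changed genes among 21319. Of changes of 1, 2 and 3 on the log2 scale it recovered 25.4%, 82.1% and 95.5% over both lines, 1.49%, 58.2% and 89.4% for HCT116 clones, 1.49%, 49.3% and 81.8% for DLD1 clones, 0%, 0% and 0% for the difference between lines in clone effect, and 37.3%, 82.1% and 95.5% for HCT116 against DLD1. Among 21119 unchanged genes it called 6, 6, 7, 0 and 15 in that order. The list test called a list shifted by 0.5 (adjusted p = 7.19e-10) and 0 of 30 unmoved lists. Simulated genes varied independently of each other. Correlations estimated for the real lists over both lines ran from -0.14 (fibroblast markers) to 0.715 (metallothioneins). The simulation therefore does not show how often lists of correlated genes are called falsely. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15.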

Results

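Gene expression was measured in HCT116 and DLD1, established human colon cancer lines, and in clones of each that resist oxaliplatin, a platinum drug that crosslinks DNA. Each line was represented by its parental culture (1 array) and 3 resistant clones (1 array each), named OHP1, OHP3 and OHP5 for HCT116 and OHP1, OHP4 and OHP5 for DLD1. Cells were harvested without drug, so the values do not describe an acute response. Each line has 1 parent array, so resistance cannot be told apart from other differences between the clones and that parent culture. Between 47.9% and 52.0% of 61657 spots were well above background on an array, the 75th percentile of the signal lay between 249 (HCT116 OHP1) and 389 (DLD1 OHP4), and 0 spots were saturated. Across genes, clones correlated with their own parent at 0.969 to 0.986, clones of a line with each other at 0.971 to 0.990, and arrays of different lines at 0.864 to 0.883. The comparisons asked, per the series title, how the clones differ from their parents and the lines from each other.

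In the resistant DLD1 clones 9 genes rose. AKR1B10, an aldo-keto reductase that reduces reactive aldehydes, rose by 5.46 ± 0.37 on the log2 scale (adjusted p = 0.00842) in all 3 clones. Its neighbours on chromosome 7 rose with it: AKR1B15, a close paralog whose probe can share signal with it, by 5.35 ± 0.40 (0.0117), and AKR1B1, aldose reductase, by 3.12 ± 0.34 (0.0308). ALDH3A1, an aldehyde dehydrogenase, rose by 2.50 ± 0.24 (0.0185), and SRXN1, sulfiredoxin, which repairs oxidised peroxiredoxins, by 2.42 ± 0.23 (0.0182). WNT5A, a secreted Wnt ligand, was well above background in the 3 clones and not in the parent, at least 59.7-fold higher (0.00842). The other genes that rose were CYP4F3, a cytochrome P450 that inactivates leukotriene B4 (4.16 ± 0.38, adjusted p = 0.0182), JAKMIP3, a microtubule-binding protein (at least 22.6-fold, 0.0185), and CD163, a scavenger receptor for haemoglobin (at least 3.35-fold, 0.0224). On hg19 the probes lay on chromosome 7 at 134225939 to 134225998 for AKR1B10, 134262468 to 134262527 for AKR1B15 and 134130061 to 134132097 for AKR1B1, and on chromosome 3 at 55499800 to 55499859 for WNT5A.

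In total 9 genes rose and 46 fell among 21326 in the DLD1 clones (limma, adjusted p under 0.05). Of the 46, 43 were well above background on the parent array alone. CCDC22, which takes part in endosomal sorting, fell (adjusted p = 0.0118), the parent being at least 17.8-fold above the clones, and was measured on 5 arrays in all. The other named genes that fell were measured on the DLD1 parent array alone, and the parent exceeded the clones by the following bounds. These were SLC9B1, a sodium-proton exchanger (at least 8.72-fold, adjusted p = 0.00445), ZNF415, a zinc finger protein (at least 4.03-fold, 0.00603), HYDIN, a protein of motile cilia (at least 3.91-fold, 0.00842), and MAS1, a G protein-coupled receptor (at least 3.46-fold). FCGR3A, an immunoglobulin receptor, exceeded them at least 2.69-fold, SERPINA4, kallistatin, at least 2.67-fold, and the small nucleolar RNA SNORD114-14 at least 2.04-fold. For PLD5, NEFH, a neurofilament protein, and PRR23A the bounds were 1.62, 1.58 and 1.42. The 43 parent spots had a median pixel variation of 0.565, against 0.354 to 0.395 in random sets of equally bright spots, and singling out OHP1, OHP4 or OHP5 in place of the parent gave 103, 61 and 32 fallen and 29, 1 and 2 risen genes, each against a group that holds the parent. With the filter of at least 3 arrays those calls numbered 25, 1 and 0, against 4 for the parent.

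Counts in the DLD1 comparison rested on few arrays. Requiring a gene to be well above background on at least 3 arrays, a filter added after seeing the data, left 4 calls (AKR1B10, AKR1B15, WNT5A and CCDC22, each with adjusted p = 0.0348). CYP4F3, AKR1B1, ALDH3A1 and SRXN1, above background on all 8 arrays, were not removed by this filter but did not pass under it. Among genes above background on all 8 arrays they passed, at the same log2 differences. JAKMIP3 and CD163, above background on 3 arrays, were also kept by the filter of at least 3 and did not pass. AKR1B10 stayed at 5.46 ± 0.37 under that filter, while its adjusted p went from 0.00842 to 0.0348. A Benjamini-Hochberg value depends on the other genes tested, and the main fit included the 43 calls lit on the parent array alone. With normexp background correction 8 genes rose and 2 fell, and 18, 5 and 8 genes passed without OHP1, OHP4 and OHP5, 14 without HCT116 OHP3 and 25 without HCT116 OHP5. AKR1B10 had adjusted p = 0.0556 without OHP4, WNT5A 0.0523 without OHP5, and SRXN1 0.0738, 0.0958 and 0.116 without OHP1, OHP4 and OHP5. Among probes that passed the filter, those of 1 named gene, SLC9B1, disagreed in sign. Without a filter on dim probes another probe stood for HYDIN and for PLD5, and the sign of both reversed.

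The glutathione and NRF2 list, enzymes of glutathione metabolism and targets of the antioxidant transcription factor NRF2, lay higher in every DLD1 clone. Of its 34 measured members 28 were above the parent, with a median of 0.93 (camera adjusted p = 1.48e-18, and adjusted p = 0.324 with an estimated correlation). AKR1B10 and SRXN1 rose over all genes and 12 members rose adjusted over the list alone. GCLC, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, differed by 1.33 ± 0.21 (adjusted p = 0.159) and GSR, glutathione reductase, by 1.17 ± 0.19 (0.184). The list median was 0.92, 0.78 and 0.82 in OHP1, OHP4 and OHP5, above all 10000 random lists of like level in each. With any DLD1 clone set against the other DLD1 arrays, the parent among them, this list did not pass (adjusted p = 0.0778, 0.638 and 0.0502 for OHP1, OHP4 and OHP5).

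**Figure D1:**
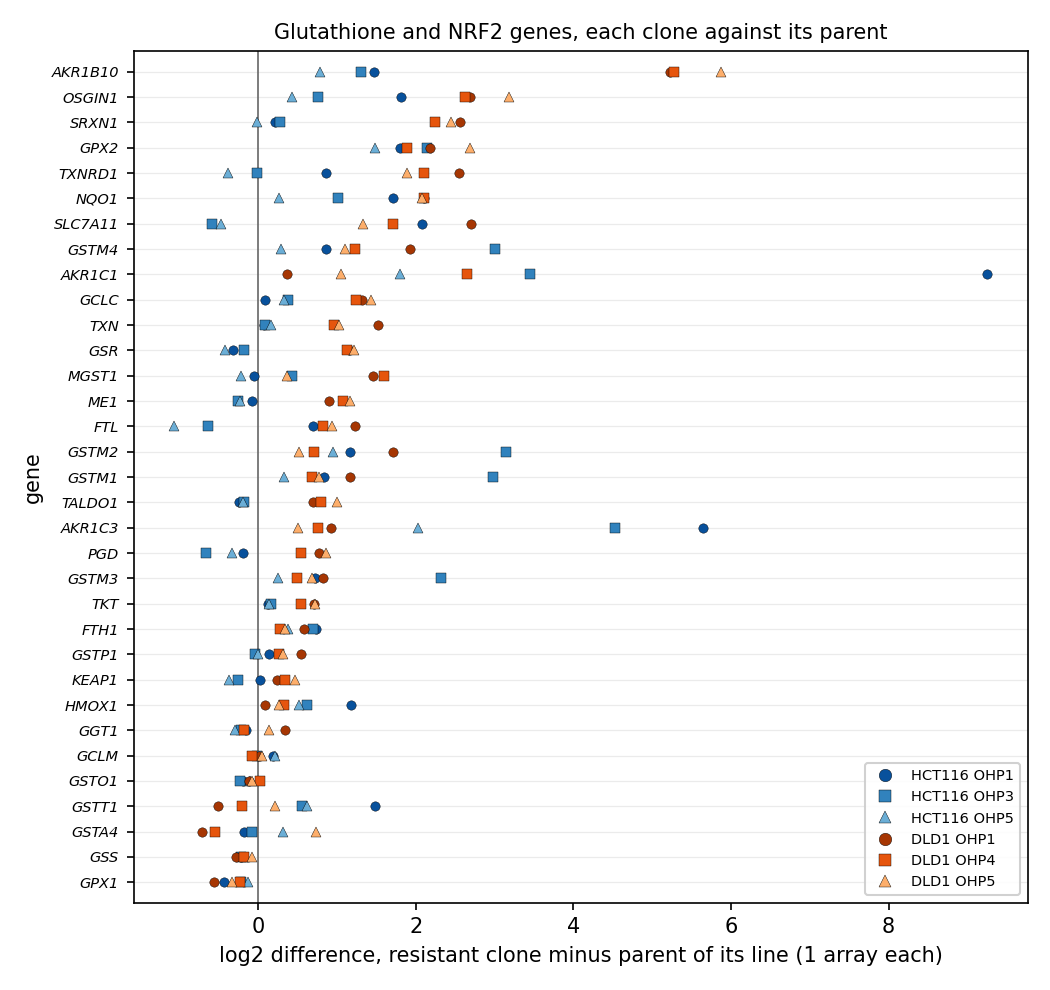
Log2 difference of the measured members of the glutathione and NRF2 list but 1, resistant clone minus the parent of its line, 1 array each. Points are the 6 clones, and AKR1B10 reached 5.23, 5.28 and 5.87 in DLD1 OHP1, OHP4 and OHP5. Of the 34 measured members of the list, 2 were never above background in HCT116. Another 2 were below it in the HCT116 parent or in all HCT116 clones, so such differences rest on background.

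Markers of colonic differentiation lay lower in the DLD1 clones. Of 29 members 24 were below the parent, with a median of -0.54 (camera adjusted p = 0.00227, and adjusted p = 0.662 with an estimated correlation), and 0 passed by themselves. The members with the largest statistics were LGALS4, a galectin of the gut lining (-2.03 ± 0.56), HEPH, an iron oxidase (-2.18 ± 0.63, above background in 1 of 3 clones), VIL1, villin of the brush border (-2.72 ± 1.27), and AGR2, a mucin-folding protein (-0.57). The median was -0.84, -0.43 and -0.22 in OHP1, OHP4 and OHP5, and -0.33 over the clones with normexp background correction.

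Another 4 lists passed camera in the DLD1 clones, and each lost its call without OHP1. They were the NF-kB and inflammation list (22 of 26 members higher, median 0.82, adjusted p = 0.00772), the unfolded protein response and ATF4 list (30 of 38, 0.17, 0.0061), the hypoxia and glycolysis list (24 of 32, 0.19, 0.0108) and 4 neural markers (4 of 4, 0.60, 0.0347, or 0.0726 without HCT116 OHP5). With an estimated correlation the adjusted p = 0.958, 0.958, 0.795 and 0.662. Without OHP1 their medians were 0.06 (adjusted p = 0.981), 0.07 (0.188), 0.14 (0.188) and 0.43 (0.089). The NF-kB median was 0.50 with normexp background correction, and 1.75 in OHP1, 0.10 in OHP4 and -0.02 in OHP5. Its leading members were RELB (1.15) and NFKB2 (1.01), subunits of NF-kB, their inhibitor NFKBIE (0.90), and the cytokine IL32 (at least 5.33-fold higher in the clones). Of the ATF4 targets, STC2, a secreted glycoprotein, was above background in 1 clone and not in the parent, SLC7A11, the cystine transporter that feeds glutathione synthesis, differed by 1.92 ± 1.10, its partner SLC3A2 by 0.93, and HERPUD1, of protein degradation at the endoplasmic reticulum, by 0.47. The glucose transporter SLC2A1 differed by 1.19 ± 0.52, EGLN3, an oxygen sensor, by 1.12 ± 0.36, and the glycolytic enzymes ALDOA and PGK1 by 0.51 and 0.33. The neural markers were MAP2 (1.21 ± 0.41), TUBB3 (0.62), ENO2 (0.58) and SNAP25 (0.32). No member of these 4 lists passed by itself over all genes. Singling out OHP1, OHP4 or OHP5 in place of the parent called 7, 6 and 4 lists, against 6 for the parent, so singling out 1 clone, against a group that holds the parent, also gave list calls of like number.

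In HCT116 the clones shared a raised interferon-response list and lower ribosomal protein genes, while few single genes passed. Of 41 measured interferon-response genes 38 were above the parent, with a median of 1.21 (camera adjusted p = 7.87e-12, and adjusted p = 0.562 with an estimated correlation). HERC6, a ubiquitin ligase, was at least 3.71-fold higher in the clones (adjusted p = 0.135). IFIT3, an antiviral protein, differed by 2.92 ± 0.62 (0.226), MX1, an antiviral GTPase, by 1.82 ± 0.40 (0.236), and RIGI, a sensor of viral RNA, by 1.28 ± 0.28 (0.232). With 5 members below background on the parent array at their bound the median was 1.19. Over all genes 0 members passed, and 10 rose adjusted over the list alone. The list median was 1.16, 1.77 and 0.53 in OHP1, OHP3 and OHP5. Singling out 1 of these clones against the rest of the line, the parent among them, gave -0.39 (adjusted p = 0.3), -1.21 (8.36e-21) and 0.50 (0.00861) for the others, and called 3, 10 and 7 lists against 15 for the parent. A gap as large as that to the parent thus also set OHP3 apart.

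**Figure D2:**
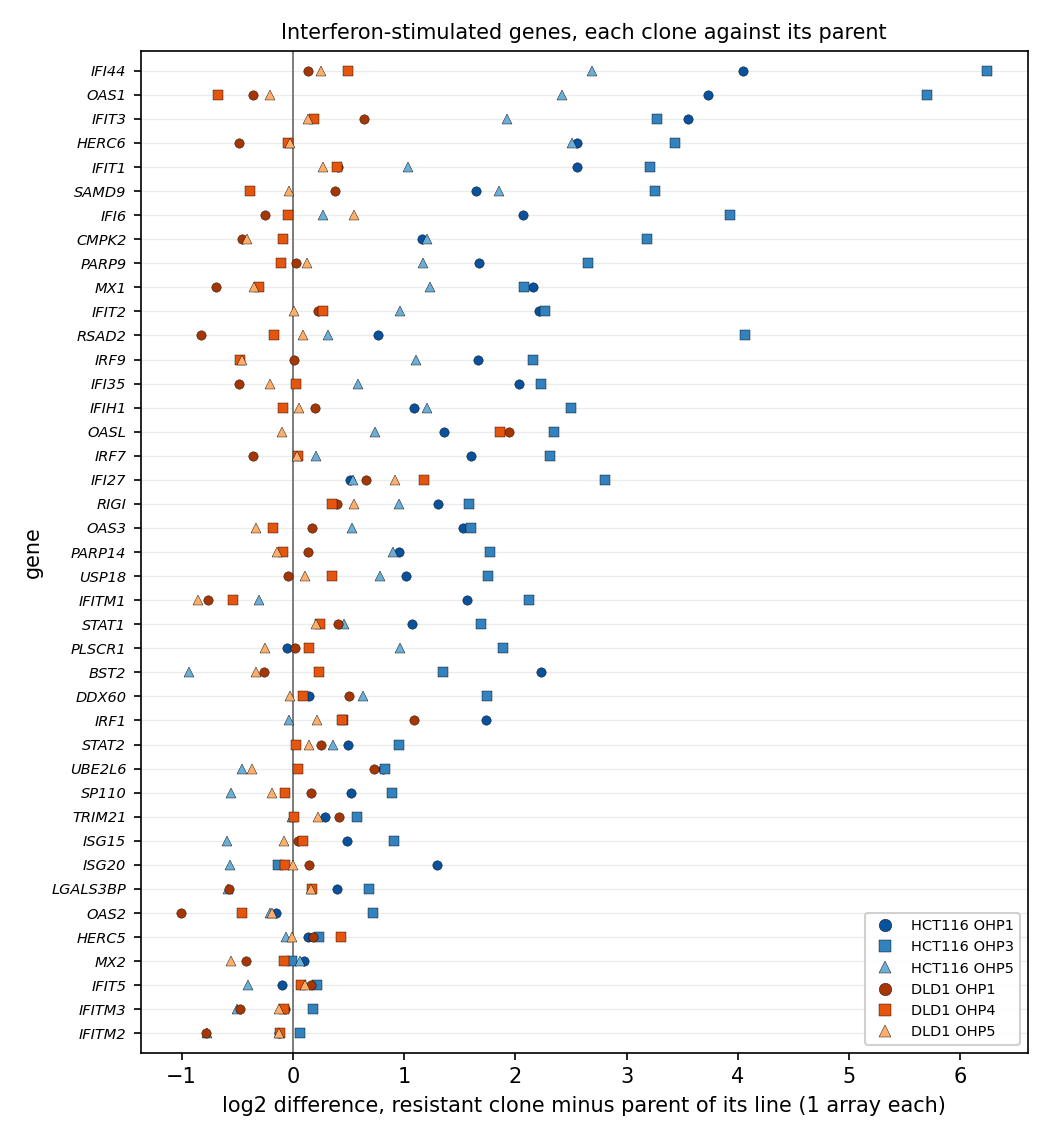
Log2 difference of each measured interferon-response gene, resistant clone minus the parent of its line, 1 array each. In the HCT116 clones IFIT1 reached 2.55, 3.21 and 1.04 in OHP1, OHP3 and OHP5 (5 other members, below background on the HCT116 parent array, have a difference that rests on background), while the list medians of the DLD1 clones lay between -0.02 and 0.13.

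Of 43 ribosomal protein genes 42 were below the HCT116 parent, with a median of -0.41 (camera adjusted p = 2.11e-07, and adjusted p = 0.562 with an estimated correlation). With quantile normalization the median was -0.17 (adjusted p = 0.00794). Members included RPL14 (-0.89 ± 0.20), RPS24 (-0.93 ± 0.26), RPL4 (-0.64) and RPL18 (-0.53), and 0 passed by themselves. In single clones the medians of -0.44, -0.53 and -0.28 stayed at percentiles 3.13, 8.46 and 33.1 of random lists of like level. Most of these random lists lay between -0.45 and -0.14, -0.56 and -0.29, and -0.35 and -0.15. Other highly expressed genes thus also lay below the parent, though mostly less so in OHP1 and OHP3. The antigen presentation list lay higher, with 19 of 24 members above the parent and a median of 0.60 (camera adjusted p = 0.000435, and adjusted p = 0.562 with an estimated correlation). HLA-DRA, a class II chain, was at least 3.07-fold higher in the clones, and the peptide-trimming enzymes ERAP1 and ERAP2 differed by 1.21 and 1.42, and the proteasome subunit PSMB10 by -0.59. Colonic differentiation markers lay higher too, in 24 of 29 members, with a median of 0.46 (camera adjusted p = 0.00246, and adjusted p = 0.562 with an estimated correlation). That median was 0.34 with 7 members at their bound and 10 never above background in HCT116 left out. MUC13, a membrane mucin, was at least 1.99-fold higher (adjusted p = 0.187), and the trefoil factors TFF2 and TFF3 at least 19.9-fold and 1.17-fold, while CEACAM1, an adhesion molecule, differed by 2.26 ± 0.70. Over all genes 0 members of these lists passed, and 1 colonic marker rose adjusted over the list alone.

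A further 5 lists passed camera as higher in the HCT116 clones, with smaller shifts. The glutathione and NRF2 list had a median of 0.15 (adjusted p = 0.0109, 24 of 34 members higher), the epithelial adhesion list 0.19 (0.0134, 23 of 36), the receptor tyrosine kinase list 0.18 (0.029, 25 of 38; 0.11 without 2 members never above background in HCT116), the mesenchymal list 0.13 (0.0348, 18 of 32) and the platinum and copper transport list 0.28 (0.0442, 9 of 11). Epithelial adhesion lay below the parent in OHP1 (median -0.23, 14 of 36 members above 0), against 0.57 and 0.32 in OHP3 and OHP5, and mesenchymal genes were at -0.07 in OHP5. The first had adjusted p = 0.562 with an estimated correlation, as had the receptor tyrosine kinase, mesenchymal and transport lists, and epithelial adhesion had 0.614. GPX2, a glutathione peroxidase, was at least 3.50-fold higher (adjusted p = 0.225), and AKR1C3, a ketosteroid reductase, differed by 4.07 ± 1.22 (0.302), AKR1B10 by 1.19 ± 0.37 and the haem oxygenase HMOX1 by 0.77. LOXL2, a matrix-crosslinking oxidase, differed by 2.27 ± 0.40 (0.164), TGFBI, a matrix protein, by 4.34 ± 1.35 (0.306), the matrix protein TNC by at least 1.12-fold and SNAI1, a repressor of epithelial genes, by -0.62. Among adhesion genes DSC2 and DSG2 of desmosomes differed by 1.46 and 0.76, the transcription factor ELF3 by 0.85 and LSR, of tricellular junctions, by 0.78. Growth signalling members were BTC, an epidermal growth factor receptor ligand (2.20 ± 0.38, 0.159), the ephrin receptor EPHA4 (2.71 ± 0.51, 0.187), the ligand NRG1 (-1.97 ± 0.35, 0.175) and the phosphatase DUSP4 (0.83). Transport members were the organic cation carrier SLC22A4 (at least 2.76-fold), the copper chaperone ATOX1 (1.28 ± 0.59), the metal reductase STEAP3 (-1.38 ± 0.56) and the copper exporter ATP7A (0.57). Adjusted over the list alone, 1 mesenchymal gene rose, and 2 growth signalling genes rose and 1 fell. The NRF2 median stayed at 0.15 with 2 members at their bound and 2 never above background in HCT116 left out.

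Another 6 lists passed camera as lower in the HCT116 clones. The metallothioneins, small metal-binding proteins, had a median of -1.14 (adjusted p = 0.00869, 8 of 10 members lower), with MT1M (-1.55 ± 0.36), MT1H (-1.42), MT1A (-1.29) and MT1E (-1.24). Base excision repair had a median of -0.38 (0.0305, 14 of 19), with the glycosylases MUTYH (-0.79), OGG1 (-0.66) and NTHL1 (-0.61) and PARP2 (-0.75), a sensor of DNA breaks. Cholesterol synthesis had -0.36 (0.0348, 21 of 25), with SQLE (-1.25 ± 0.37), DHCR7 (-0.92), IDI1 (-0.71) and CYP51A1 (-0.65), enzymes of the pathway. Nucleotide metabolism had -0.33 (0.0393, 21 of 29), with the kinase UCK2 (-1.22 ± 0.25), the folate carrier SLC19A1 (-1.07 ± 0.20), the nucleoside carrier SLC29A1 (-1.07) and the folate hydrolase GGH (0.74). The unfolded protein response and ATF4 list had -0.29 (0.0442, 26 of 38), with the amino acid carrier SLC7A5 (-1.35 ± 0.32), the biosynthetic enzymes PSAT1 (-1.31 ± 0.27) and MTHFD2 (-1.21 ± 0.24), and the pseudokinase TRIB3 (-0.94). The cell cycle list had -0.26 (0.0455, 38 of 51), with the replication helicase subunits MCM7 (-0.85 ± 0.20), MCM6 (-0.77) and MCM2 (-0.62) and the transcription factor MYBL2 (-0.80). With an estimated correlation the adjusted p = 0.562 for metallothioneins, base excision repair and nucleotide metabolism, 0.614 for cholesterol synthesis and the ATF4 list, and 0.652 for cell cycle. Over all genes 0 of these members passed. Against random lists of like level, OHP1, OHP3 and OHP5 lay at percentiles 91.2, 2.3 and 29.4 for cell cycle, 41.1, 10.4 and 0.04 for nucleotide metabolism, 73.9, 4.15 and 0 for the ATF4 list, 0.66, 0.795 and 51.2 for cholesterol synthesis, 2.59, 0.06 and 0.3 for base excision repair, and 6.03, 0 and 0 for metallothioneins. Reference genes also lay lower (median -0.28, 12 of 15) without passing (0.154). Adjusted over the list alone, 1 metallothionein, 2 nucleotide metabolism genes and 2 ATF4 list genes fell.

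Of the 15 list calls in HCT116, 4 held in each of 10 alternatives besides the estimated correlation: interferon response, antigen presentation, colonic differentiation and ribosomal proteins. Leaving out OHP3 ended those of platinum transport (adjusted p = 0.111), metallothioneins (0.0501), base excision repair (0.0725), epithelial adhesion (0.248), mesenchymal genes (0.06), cell cycle (0.287), nucleotide metabolism (0.0554), the ATF4 list (0.0886), cholesterol synthesis (0.123) and growth signalling (0.0618). Without OHP1 the mesenchymal and cholesterol lists had adjusted p = 0.119 and 0.125, and without OHP5 the platinum, epithelial, cell cycle, nucleotide and ATF4 lists had 0.102, 0.102, 0.0714, 0.108 and 0.153. Without DLD1 OHP1 cell cycle had 0.0578. Quantile normalization ended the calls of cell cycle (median -0.02, adjusted p = 0.597), the ATF4 list (-0.16, 0.515), nucleotide metabolism (-0.17, 0.238), cholesterol synthesis (-0.16, 0.154) and base excision repair (-0.27, 0.0507). Normexp background correction ended those of the NRF2 list (0.115), platinum transport (0.125), epithelial adhesion (0.0566) and growth signalling (0.0737). Some medians grew instead: with quantile normalization the NRF2 list had 0.35 (adjusted p = 0.000154) and epithelial adhesion 0.31 (0.00103), without OHP5 the NRF2 list had 0.24 (0.00173), without OHP1 epithelial adhesion had 0.43, and the mesenchymal list had 0.24 (0.0261) without OHP5.

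Single genes that passed in the HCT116 clones numbered 4 of 21331, 1 higher and 3 lower (limma). LOC400706, an uncharacterised transcript named here after its values were seen, was at least 7.69-fold higher in the clones (adjusted p = 0.0193) and was below background on the parent array alone. VHRT, a noncoding transcript with a probe on chromosome 12 at 111375193 to 111375252, fell by 3.63 ± 0.26 on the log2 scale (0.0301). LIN28B, an RNA-binding protein that blocks let-7 maturation, was measured on the parent array alone, at least 2.73-fold above the clones (0.0301). The remaining gene that fell is Y-linked and by the fixed rule is not described. Genes with the next largest statistics did not pass: HOXA3, a homeobox factor (3.39 ± 0.31, 0.0625), MAST4, a kinase (3.33 ± 0.31, 0.0625), PLEKHA6 (1.81 ± 0.19, 0.0775), TPTEP2 (at least 1.45-fold, 0.0885), the histone gene H2BW2 (at least 3.02-fold, 0.0502), and, measured on the parent array and in no clone, the zinc finger protein ZNF423 (parent at least 1.51-fold higher, 0.0625), DTHD1 (1.33-fold, 0.0676) and SMIM43 (1.13-fold, 0.089). At an unadjusted p under 0.05 there were 2785 genes, or 13.1%, against 784, or 3.68%, in the DLD1 clones (limma). Both contrasts share 1 estimate of the spread. Clones of HCT116 differed more from each other (standard deviations of 0.61 to 0.78) than clones of DLD1 (0.45 to 0.61). The higher share in HCT116 thus does not by itself show a larger clone effect. Singling out OHP1, OHP3 or OHP5 against the rest of the line, the parent among them, called 45, 0 and 23 genes. With the filter of at least 3 arrays far fewer genes were called for OHP1 and OHP5. The count was 50 without OHP1, 0 without OHP3, 1 without OHP5, 2 without DLD1 OHP4 and 0 without DLD1 OHP5, and the split was 7 higher and 7 lower with normexp background correction and 2 higher and 3 lower with the series matrix values.

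Over both lines together, with 6 clones against 2 parents, 0 of 21331 genes passed (limma, lowest adjusted p = 0.349). An unadjusted p under 0.05 was reached by 1241, or 5.82%. The genes with the largest statistics did not pass. They were CYP4F3 (3.31 ± 0.40), GPX2 (2.03 ± 0.27) and ABTB3 (1.23 ± 0.16), the last 2 above background in 1 of 2 parents, the vesicle-trafficking GTPase RAB15 (1.13 ± 0.14) and ACP4 (at least 1.73-fold), each with adjusted p = 0.349. In the other direction they were AOX2P, measured on 1 parent array alone (0.591), the taste receptor TAS2R45 (parents at least 1.08-fold higher, 0.677), the membrane protein STOM (-1.25 ± 0.24, 0.687), KIAA0485 (-1.54 ± 0.30, 0.687) and the histone gene H2AC13 (-0.89 ± 0.18, 0.733). The glutathione and NRF2 list lay higher in the clones of both lines, with 29 of 34 members above the parents and a median of 0.55 (camera adjusted p = 2.35e-11, and adjusted p = 0.547 with an estimated correlation), and 4 members rose adjusted over the list alone. AKR1B10 differed by 3.33 ± 0.82 (adjusted p = 0.789) in this comparison. The list median was larger in DLD1, at 0.93, than in HCT116, at 0.15. Members above the parent numbered 29, 28 and 31 of 34 in DLD1 OHP1, OHP4 and OHP5. In HCT116 OHP1, OHP3 and OHP5 they numbered 24, 18 and 19. Against random lists of like level these 3 HCT116 clones still lay at percentiles 100, 99.95 and 99.98. Most of those random lists lay between -0.34 and 0.08, -0.41 and -0.02, and -0.29 and 0.02.

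The other lists that passed over both lines lost their call without the parent of 1 line. Without the HCT116 parent, which leaves the DLD1 contrast, no call was left for interferon response (median 0.65, adjusted p = 2.13e-08, against 0.02 and 0.92 without it), antigen presentation (0.41, 0.000471, against 0.14 and 0.676), metallothioneins (-0.71, 0.000669, against -0.29 and 0.0807), cholesterol synthesis (-0.29, 0.00133, against -0.13 and 0.0777) or ribosomal proteins (-0.24, 1.58e-06, against -0.04 and 0.525). Without the DLD1 parent the NF-kB list went from 0.45 (0.000669) to 0.42 (0.0647) and the neural markers from 0.31 (0.0297) to 0.17 (0.206). With an estimated correlation the adjusted p = 0.561 for cholesterol synthesis and 0.547 for the rest. A lost call does not show that the lines differed. On the mean of the DLD1 clones 9 of 10 metallothioneins and 22 of 25 cholesterol synthesis genes also lay below the parent. Cholesterol synthesis genes above the DLD1 parent numbered 1, 18 and 8 of 25 in DLD1 OHP1, OHP4 and OHP5. Their medians were -0.54, 0.08 and -0.09, so a fall was not shared by all DLD1 clones. Metallothioneins above it numbered 4, 1 and 1 of 10, with medians of -0.10, -0.52 and -0.39. The difference between lines did not pass for metallothioneins (adjusted p = 0.138), cholesterol synthesis (0.569), the NF-kB list (0.992) or neural markers (0.992). The neural call also ended without HCT116 OHP1 (0.0753) and HCT116 OHP5 (0.0583).

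Repair, efflux and cell death lists did not pass over both lines. Median differences were 0.29 for ABC efflux pumps (adjusted p = 0.254), -0.04 for nucleotide excision repair (0.852), -0.20 for mismatch repair (0.229), -0.14 for base excision repair (0.0642, 16 of 19 lower), -0.11 for homologous recombination and Fanconi genes (0.111), -0.07 for translesion synthesis (0.466), 0.09 for apoptosis genes (0.0642) and 0.18 for WNT targets (0.0998). Markers of other cell types gave -1.02 for 3 fibroblast genes (0.466; 0 with 1 member at its bound, so the value rests on background), -0.00 for 8 blood genes (0.449) and 0.07 for 5 endothelial genes (0.361). Cancer-testis antigens had a median of 0.00 (0.612) and reference genes -0.04 (0.988). The blood, cancer-testis and reference lists had medians, means and tests that differed in sign, as had the hypoxia (-0.02, 0.202), ATF4 (-0.03, 0.92) and receptor tyrosine kinase (-0.02, 0.273) lists.

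**Figure D3:**
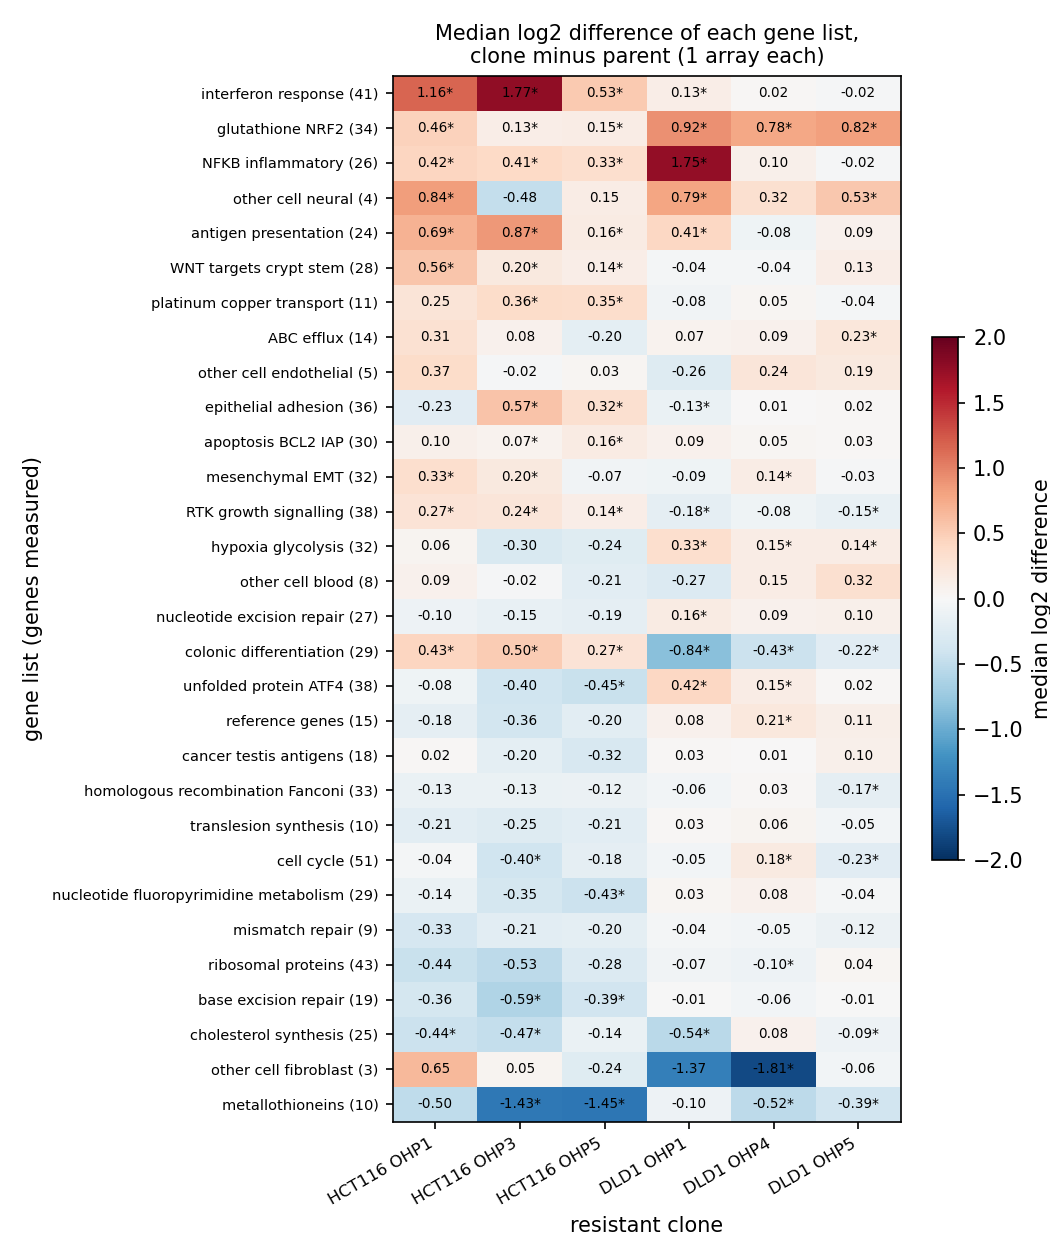
Median log2 difference of 30 of the 31 gene lists, clone minus the parent of its line, 1 array each, with colour from low to high. The NRF2 list is above 0 in all 6 clones, from 0.13 in HCT116 OHP3 to 0.92 in DLD1 OHP1.

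The genes fixed in advance for platinum transport, repair and cell death differed between clones and parents by varied amounts. None of the 15 genes fixed in advance passed in either line or over both lines (limma). The copper carrier SLC31A1, which takes up platinum drugs, differed by 0.06 in HCT116 and 0.14 in DLD1, the copper exporters ATP7A by 0.57 and 0.03 and ATP7B by 0.12 and -0.52 ± 0.24, and the platinum-conjugating enzyme GSTP1 by 0.04 and 0.37 ± 0.21. Efflux pumps varied more between clones: ABCB1, above background in 1 of 3 HCT116 clones, differed by 0.10 ± 0.98 and 0.59 ± 0.98, and ABCC2 by -0.71 ± 1.04 and 1.93 ± 1.04. The excision repair genes ERCC1 (-0.28 and 0.32) and XPA (0.15 and 0.12) and the mismatch repair gene MSH6 (-0.40 ± 0.19 and -0.11) did not pass either. MDM2, a ubiquitin ligase, differed by 0.19 and -0.06, BAX, a cell death effector, by 0.10 and 0.28, and CDKN1A, a cell cycle inhibitor, by -0.02 in HCT116 and at least 1.71-fold in DLD1 (adjusted p = 1). Over both lines the values were between -0.26 ± 0.14 for MSH6 and 0.82 for CDKN1A.

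**Figure D4:**
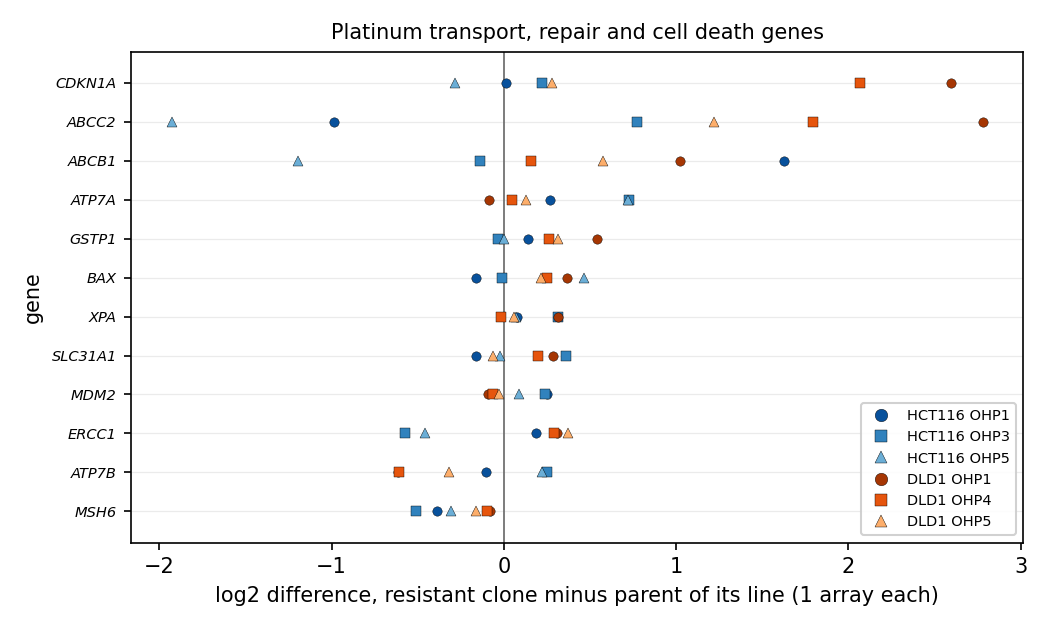
Log2 difference of 12 of the genes fixed in advance, resistant clone minus the parent of its line, 1 array each. Points are the 6 clones, and genes such as ABCC2 and ABCB1 differ more between clones than SLC31A1 or XPA do.

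The clone effect, clones minus parent, differed between the lines for 23 of 21326 genes, 18 with a more positive and 5 with a more negative difference in HCT116 (limma interaction). WNT5A, raised in the DLD1 clones, gave -6.23 ± 0.63 (adjusted p = 0.0448), and VHRT and LIN28B, lower in the HCT116 clones, gave -3.68 and -3.62. The positive side held genes measured on 1 array in 17 of its 18 cases, among them ZNF415 (4.47 ± 0.35, 0.027), SLC9B1 (4.37 ± 0.34, 0.027), HYDIN (4.23, 0.0372), FCGR3A (3.72) and PLD5 (3.43, 0.0472), which had fallen in the DLD1 clones. For genes below background in a group these values rest on the background signal and are no folds. The genes with the next largest statistics, AKR1B10 (-4.27 ± 0.53, 0.0675) and AKR1B15 (-4.53 ± 0.57, 0.0711), did not pass. With any 1 of HCT116 OHP3, HCT116 OHP5 or the 3 DLD1 clones left out, 0 genes passed, and without HCT116 OHP1 64 did. At an unadjusted p under 0.05 there were 1684, or 7.9%, and a filter of all 8 arrays above background also left 0. The split was 4 higher and 8 lower with normexp background correction and 38 higher and 5 lower with the percentile over detected probes.

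Gene lists moved apart between the lines in the same comparison. Colonic differentiation genes (median 1.09, camera adjusted p = 8.64e-06) and interferon-response genes (1.0, 1.24e-08) were shifted upward in HCT116 relative to DLD1, as were receptor tyrosine kinase genes (0.37, 0.0134), antigen presentation genes (0.34, 0.0169) and epithelial adhesion genes (0.21, 0.0386). The NRF2 list (-0.48, 0.00277), the ATF4 list (-0.52, 0.00173), ribosomal proteins (-0.37, 0.000149) and reference genes (-0.31, 0.0386) were shifted downward in HCT116. With members at their bound the colonic and interferon medians were 0.80 and 0.85. With an estimated correlation the adjusted p = 0.565 for the colonic, growth signalling and reference lists, 0.719 for the interferon, NRF2 and ATF4 lists, 0.799 for antigen presentation and ribosomal proteins, and 0.856 for epithelial adhesion. Quantile normalization left -0.12 (adjusted p = 0.256) for ribosomal proteins and -0.06 (0.699) for reference genes, with 0.43 for epithelial adhesion and 0.60 for antigen presentation, and without HCT116 OHP3 epithelial adhesion had a median of -0.04 (0.359). Epithelial adhesion also lost its call without HCT116 OHP5 (0.186) or DLD1 OHP1 (0.083), antigen presentation without HCT116 OHP3 (0.0629) or DLD1 OHP4 (0.0684), and reference genes without HCT116 OHP3 (0.1), HCT116 OHP5 (0.0622), DLD1 OHP1 (0.0671) or DLD1 OHP4 (0.062).

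Few differences of the clones from their parents were shared by the lines. In all 3 clones, 360 genes were at least 2-fold higher and 300 lower than the HCT116 parent, and 173 higher and 235 lower than the DLD1 parent, against a mean of 259 and a maximum of 301 in either direction together in 100 simulations of unchanged arrays. The simulations did not model the filter, which lets in genes lit on a parent array alone. They also used 1 spread for both lines. The log2 differences between clones had standard deviations of 0.61 to 0.78 in HCT116 and 0.45 to 0.61 in DLD1. Of these genes 342 higher and 195 lower in HCT116, and 156 higher and 80 lower in DLD1, were well above background on at least 3 arrays. The DLD1 counts can therefore not be read as an excess over unchanged arrays. With the shared spread the simulated level may be too low for HCT116 and too high for DLD1. Genes higher in all 6 clones numbered 14, where 2.92 would be shared by independent lists, and genes lower in all 6 numbered 6, against 3.31. Among the 14 were GPX2, the leukotriene-degrading enzymes CYP4F2 and CYP4F3, the apoptosis inhibitor BIRC7, the adhesion molecule FLRT3, CLIP4, CD3E and FBXW10. Named genes among the 6 were CSTA, an inhibitor of cysteine proteases, the scavenger receptor MSR1, and SAMD13. These shared genes were listed after their values were seen. Opposite directions were shared by 6 genes (3.97 by independent lists) and by 4 (2.43), and 0 genes were called by limma in both lines. Across 21326 genes, which are not independent replicates, the differences in the lines correlated with r = 0.0222 and rho = 0.0113. Over the 15566 genes above background on all 8 arrays these were 0.0598 and 0.0469. With genes above background on all 8 arrays alone, 246 and 72 genes were 2-fold apart in all 3 HCT116 and DLD1 clones, 3 of them shared, and with normexp background correction 49 were higher and 31 lower in DLD1.

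Single clones differed from their parents by at least 2-fold in more genes in HCT116 than in DLD1. In OHP1, OHP3 and OHP5 of HCT116, 1612, 1400 and 948 genes were higher and 1460, 1387 and 1610 lower. In OHP1, OHP4 and OHP5 of DLD1, 772, 510 and 516 were higher and 1216, 709 and 740 lower. Each value compares 1 array with 1 array and has no replicate check. Median scaling gave 986 higher and 2862 lower in HCT116 OHP1 and 1162 and 1347 in HCT116 OHP5, and normexp correction gave 343 and 294 in the latter, 260 and 242 in DLD1 OHP1 and 102 and 76 in DLD1 OHP5.

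HCT116 and DLD1 differed in 8172 of 21331 genes, 3773 higher in HCT116 and 4399 higher in DLD1 (limma, 4 arrays each), of which 4646 differed at least 2-fold. The genes that differed most in favour of HCT116 were dim or below background in DLD1. ADIRF, a fat cell differentiation factor, was higher (adjusted p = 4.1e-07) and above background on 2 of 4 DLD1 arrays, and GTSF1, a germ cell factor of transposon silencing, at least 861-fold. MAGEA6 and MAGEA2B, cancer-testis antigens, were at least 714-fold and 619-fold higher (2.09e-08 for the latter), DKK1, a secreted Wnt inhibitor, at least 470-fold, MSN, moesin, which links actin to the membrane, at least 268-fold, and CD109, a surface protein that binds TGF-beta, at least 194-fold. Those that differed most in favour of DLD1 were dim or below background in HCT116. GSTM3, a glutathione transferase, was at least 2884-fold higher (5.76e-07), ASCL2, a transcription factor of intestinal stem cells, at least 1494-fold, AGR2, a mucin-folding protein, at least 1017-fold, SELENBP1, a selenium-binding protein, at least 769-fold, TM4SF1, a membrane protein, at least 624-fold, and LEF1, a partner of beta-catenin, at least 361-fold. CMTM3, PDE4B, IRX4 and NTSR1 were also among the 12 highest in HCT116, and TMEM45B, QPCT, SCCPDH, TFF3, CBR1 and ACOT1 among the 12 highest in DLD1.

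Between the lines, genes of DNA repair and drug transport differed one by one. MSH3 was lower in HCT116 by -2.82 ± 0.19 (adjusted p = 2.73e-05), and MSH6, known to be defective in DLD1, was lower in DLD1, by 2.04 ± 0.12 (1.65e-05). The mismatch repair list as a whole did not pass (median -0.38, adjusted p = 0.23), nor did ABC efflux pumps (0.03, 0.964, with 4 members higher and 5 lower). CDKN1A, above background on 2 of 4 DLD1 arrays, was higher in HCT116 by 3.48 ± 0.54 (0.00191). MDM2 was higher by 0.53 (0.0116) and ERCC1 by 0.64 (0.0459). The efflux pump ABCC2 was higher in HCT116 by 4.45 ± 0.72 (0.00248) and ABCB1, above background on 2 of 4 HCT116 arrays, in DLD1, at -5.61 ± 0.56 (0.000224). SLC31A1 (-0.67, 0.0146) and ATP7A (-0.55, 0.0385) were lower in HCT116, and XPA (0.21), ATP7B (0.00), BAX (-0.33) and GSTP1 (-0.35) did not pass.

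Of the gene lists, 6 described here passed between the lines. Cancer-testis antigens were higher in HCT116 for 9 of 18 and lower for 1 (median 1.71, camera adjusted p = 3.16e-05), with MAGEB2 at least 295-fold, CSAG2 at least 93.9-fold and MAGEA4 at least 15.2-fold, and CSAG1, above background on 1 of 4 DLD1 arrays. Metallothioneins were higher for 7 of 10 (1.0, 0.0131), with MT1M 1.39, MT1L 1.37, MT1E 1.36 and MT1B 1.20, and cell cycle genes for 16 of 51 with 4 lower (0.35, 0.0131), with the replication licensing factor CDT1 1.26, the spindle proteins TPX2 1.03 and DLGAP5 0.95, and the nucleotide reductase RRM1 -0.90. Lower in HCT116 were the NRF2 list (17 lower and 1 higher of 34, median -1.05, 0.00135), with GSTT1 at least 42.5-fold, GPX2 -3.97 (above background on 3 of 4 HCT116 arrays) and GGT1 -1.61, the colonic list (15 lower and 2 higher of 29, -1.06, or -0.54 with 10 members at their bound and -0.17 with normexp background correction, 0.00311), with the intestinal cadherin CDH17 at least 38.9-fold, TFF3 (above background on 1 of 4 HCT116 arrays) and TFF1 -3.86, and cholesterol synthesis (19 lower and 1 higher of 25, -0.84, 0.00311), with HMGCS1 -1.38, ACAT2 -1.33 and SC5D -1.24. With an estimated correlation the adjusted p = 0.805 for cell cycle and 0.757 for the rest. The cell cycle call ended without DLD1 OHP5 (adjusted p = 0.0698). The median over all genes was -0.10, against which these shifts are read.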

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

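Tests of whether 1 clone carries the NRF2 list were chosen only after the result was seen, and the other tests of this part were written before it.

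In DLD1 the clones shared higher levels of glutathione and NRF2 genes, and the interaction test of the clone effect between the lines gave this list a median difference of -0.48, HCT116 minus DLD1 (adjusted p = 0.719 with an estimated correlation). Paralogs sharing a probe were argued against, since without the aldo-keto reductase and GSTM members the 27 other genes lay at percentile 100 of random lists in each clone. A single clone was argued against too, with a lowest median of 0.78 in OHP4, as was spread between clones, since the largest difference of a DLD1 clone from the other 2 was -0.15, against 0.93 between clones and parent. Higher NRF2 activity in the clones remains open as a hypothesis: 15 further target genes, kept apart from the list, had a lowest median of 0.71 over the DLD1 clones, above all 10000 random lists. A difference between 1 parent culture and the clones that has nothing to do with resistance may give the same picture and was not tested, and parent position on the slide cannot be told apart from the parental state.

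Genes that fell in the DLD1 clones while lit on the parent array alone gave most of the difference in clone effect between the lines, which was called for 23 genes by the interaction test. The named ones with a positive difference were ZNF415 (4.47), SLC9B1 (4.37), HYDIN (4.23), FCGR3A (3.72) and PLD5 (3.43). Expression of these genes in the DLD1 parent found no support in their other probes. Of 37 such probes 0% were above background on that array and on no DLD1 clone. Each gene was represented by the probe with the highest mean among those that passed. Its other probes may lie below background even if the gene is expressed, so this test cannot exclude expression. The filter takes part by construction, since it lets in genes lit on the DLD1 parent array alone (314 tested) and none lit on 1 DLD1 clone alone (0). With the filter rebuilt, singling out a DLD1 clone in place of the parent called a median of 61 fallen genes, against 46 for the parent. Uneven spots stay open, with pixel variation at percentile 100 of equally bright spots, so these calls may come from single spots and not from the clones.

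The clone effect on WNT5A differed between the lines by -6.23 in the same interaction test, as did that on VHRT by -3.68 and that on LIN28B by -3.62. VHRT was above background on 8 arrays, WNT5A on 3 and LIN28B on 1. For the last 2 genes the values rest on background signal and are no folds.

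The same test moved lists apart, upward in HCT116 for colonic differentiation (1.09), interferon response (1.0), receptor tyrosine kinase signalling (0.37), antigen presentation (0.34) and epithelial adhesion (0.21). None of these passed with an estimated correlation (adjusted p = 0.565 for the colonic and growth signalling lists, 0.719 for interferon, 0.799 for antigen presentation and 0.856 for epithelial adhesion), and without HCT116 OHP3 the last had a median of -0.04 (adjusted p = 0.359).

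It moved others downward in HCT116, namely the unfolded protein response and ATF4 list (-0.52), ribosomal proteins (-0.37) and reference genes (-0.31). These did not pass with an estimated correlation either (adjusted p = 0.719, 0.799 and 0.565), and quantile normalization left -0.12 (0.256) for ribosomal proteins and -0.06 (0.699) for reference genes.

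Of the spike-in probes, which no comparison used, 2 were well above background on clone arrays and on no parent array. ERCC-00137_95 was so on 2 arrays, with log2 signals of 4.76 and 4.80 in DLD1 OHP4 and OHP5, against 4.23 and 4.32 in the HCT116 and DLD1 parents and 3.49 to 3.91 in the other clones. ERCC-00142_99 was above background on 4 arrays, with log2 signals of 6.90, 6.15 and 6.03 in HCT116 OHP1, OHP3 and OHP5 and 5.61 in DLD1 OHP1. Its signals were 2.13 and 2.33 in the HCT116 and DLD1 parents, and 2.52 and 2.38 in DLD1 OHP4 and OHP5. Of 96 such probes 5 were above background on at least 1 array and 1 on all 8. Each group held 1 or 3 arrays, too few to test an array for standing apart within its own group.

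Of 35 splits of the 8 arrays into 4 and 4, 1 (the real one itself, by line) called 8172 genes, against a highest of 2 in the others. The other splits mix the lines, so the line difference enters their spread and few calls follow by construction. Arrays of a line are also a parent and its own clones, so these splits cannot exclude chance. The split by line is also the split by slide row.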

How the results depend on the processing

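The filter of at least 3 arrays, the common floor, and the percentile over detected probes were added after seeing the data, and the other alternatives were planned. Clone numbers were not treated as pairs, since the lines shared 2 numbers alone and deviations of same-number clones correlated at 0.0102 and 0.0555, against -0.0665 to 0.0521 for the others. A replicate block on the number called 4526 genes between the lines and 0 over both lines. The block was not fitted for the comparisons within a line or their difference, and a block on the slide was not run because there was 1 slide. Signal over background limited the counts: between 47.9% and 52.0% of the spots were well above it on an array, and counts of genes 2-fold apart were higher without a filter on dim probes in each line and clone. Median scaling moved the median of all genes to -0.159 in the HCT116 clones and -0.16 in the difference between lines, against which changes under it are read. A lone parent array is assumed to vary like the clones.

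Among values of named genes 6039 kept their direction and side of the threshold or moved within their spread, 264 no longer passed, 48 newly passed, 162 moved further and 3 reversed. For 43 of the 45 list calls, counted per comparison, 383 values under the alternatives kept the call and 96 lost it, and the remaining pair follows. Interferon response in HCT116 clones (1.21, adjusted p = 0.562) and the NRF2 list in DLD1 clones (0.93, adjusted p = 0.324) lost it with an estimated correlation alone, and with an array left out they ranged from 0.851 to 1.57 and from 0.807 to 0.957. Without a filter on dim probes HYDIN (0.82) and PLD5 (0.0617) reversed in the DLD1 clones and HYDIN (-0.18) in the difference between lines, by construction, because another probe then stood for the gene. For the counts that follow the cause was not tested except where a cause is given.

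Over both lines 0 genes passed, 2 with all probes tested, and 0 to 55 with an array left out. The 55 without the HCT116 parent and 4 without the DLD1 parent follow from construction, since the contrast then rests on the other line.

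In the HCT116 clones (4 genes) the count was 14 with normexp correction, 27 with quantile normalization, 14 with median scaling, 1 without a filter, 44 with the common floor, 8 with all probes, 23 with trend and robust, 0 with the 4 arrays of that line alone, 38 at an adjusted p under 0.1, and 0 to 50 with an array left out. In the DLD1 clones (55) it was 10 with normexp, 22 without a filter, 7 with genes above background on all 8 arrays, 4 with at least 3 arrays, 89 with the common floor, 11 with trend and robust, 21 with that line alone, and 5 to 57 with an array left out. The stricter filters take out the probes lit on the parent array alone.

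For the difference between lines (23) it was 12 with normexp, 56 with quantile normalization, 62 with median scaling, 56 with the common floor, 43 with the percentile over detected probes, 14 with all probes, 73 at an adjusted p under 0.1, and 0 to 64 with an array left out. It was 0 without a filter, with all 8 arrays, with at least 3 arrays, and with trend and robust. AKR1B10 passed for this difference with normexp (0.0199), quantile normalization (0.0413) and median scaling (0.0258). Between the lines (8172) it was 4646 at 2-fold and 6343 to 7989 with an array left out.

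Genes 2-fold apart in all 3 HCT116 clones (660) numbered 194 with normexp, 1000 without a filter, 246 with all 8 arrays, 374 with the common floor, 135 at 4-fold, and 920 to 1256 with an array left out. Those in DLD1 (408) numbered 80, 794, 72, 178 and 106 in that order, 240 with at least 3 arrays, and 589 to 658 with an array left out, where fewer clones have to share the change. Shared genes (20) numbered 2 with normexp, 33 without a filter and 3 with all 8 arrays.

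For single clones the counts with normexp, without a filter and with all 8 arrays were 1152, 6002 and 1415 in HCT116 OHP1, 1011, 5413 and 1262 in OHP3, and 637, 4897 and 859 in OHP5. For DLD1 they were 502, 4389 and 561 in OHP1, 202, 3502 and 212 in OHP4, and 178, 3674 and 205 in OHP5.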

Other observations

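The chromosome 5 tests of normalization and of few genes or 1 stretch were chosen only after the result was seen, as were the genes named in the next 2 paragraphs.

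NRF2 target genes outside the fixed list lay higher in single clones of both lines. EPHX1, an epoxide hydrolase, differed from the parent by 2.39, 1.47 and 0.77 in HCT116 OHP1, OHP3 and OHP5 and by 1.37, 1.20 and 1.79 in DLD1 OHP1, OHP4 and OHP5. CBR3, a carbonyl reductase, differed by 2.78, 1.53 and 0.19 and by 1.37, 1.87 and 1.43, and the efflux pump ABCC3 by 2.84, 2.89 and 1.65 and by 0.64, 0.32 and 0.98. The median over the 15 genes was 0.72, 0.39 and 0.26 in the HCT116 clones. Within the fixed list AKR1C3 stood out in HCT116 (5.65, 4.53 and 2.04), and NQO1 (2.11, 2.10 and 2.08) and TXNRD1 (2.54, 2.11 and 1.89) in DLD1. None of these genes passed in the limma fit of its line.

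Among genes measured on all 8 arrays, PMEPA1, a target and inhibitor of TGF-beta signalling, rose in the HCT116 clones by 5.61 ± 0.57 (limma, adjusted p = 0.0481 over these genes), HOXA3 by 3.39 ± 0.29 (0.0269), MAST4 by 3.33 ± 0.29 (0.0269) and PLEKHA6 by 1.81 ± 0.18 (0.0481). These did not pass over all tested genes. Between the lines, the receptor KIT was at least 48.7-fold higher in DLD1, the immunoproteasome subunit PSMB8 at least 74.8-fold, and LGR5, a receptor of intestinal stem cells, at least 8.54-fold, while LOXL2 was at least 108-fold higher in HCT116.

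Genes of chromosomes 5 and 17 lay apart from the rest in single HCT116 clones. Medians of 23 chromosomes in 6 clones were each set against 10000 random lists matched on level, over genes above background on all 8 arrays. Chromosome 5 lay higher in HCT116 OHP1 (median 0.31 over 662 genes, 73.7% of them above 0), and chromosome 17 lower in HCT116 OHP5 (-0.26 over 964 genes), with medians of -0.31, -0.54 and -0.69 in its windows from 40 to 60, 60 to 80 and 80 to 100 Mb. Chromosome 19 passed the lowest random list by little in HCT116 OHP3 (-0.22) and DLD1 OHP1 (-0.07). Of 156 windows of 20 Mb, 5, 0 and 3 lay outside the random lists in HCT116 OHP1, OHP3 and OHP5, and 2, 0 and 1 in DLD1 OHP1, OHP4 and OHP5.

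For chromosome 5 in HCT116 OHP1, array brightness was argued against, as the median was 0.28 with quantile normalization and the highest random list 0.0758. A few genes or 1 stretch were argued against, as the 10 windows had medians from 0.16 to 0.51, with 9 of them at percentile 98.8 or above and the last, of 26 genes, at 89.4. An extra copy of the chromosome in that clone may account for the shift, a hypothesis that the tests leave standing: the dimmest, middle and brightest of its genes, in groups of like number, had medians of 0.36, 0.33 and 0.23. Copy number was not measured, and the clone is 1 array.

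Medians, means and tests differed in sign for translesion synthesis (median 0.02) and mesenchymal genes (0.01) in the DLD1 clones and for blood markers (-0.07) in the HCT116 clones. In the difference between lines this held for ABC efflux (-0.18), apoptosis (-0.02) and neural markers (-0.28), and between the lines for ABC efflux (0.03), antigen presentation (0.01), nucleotide metabolism (-0.02) and hypoxia (-0.02).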
